A study of Mus musculus with 30 samples.

How the data were processed

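Gene-level values of 30 bulk RNA libraries were read from the deposited tables: 5 libraries in each of 6 groups, iWAT and BAT of male C57BL/6J mice at 22 °C, after 6 h at 6 °C and after 24 h at 6 °C. The submitters' notes name HISAT2, HTSeq and the mouse assembly GRCm39, without versions. The deposited counts were whole numbers of assigned reads per gene made by the authors, with no scaling. The deposited FPKM were values the authors had divided by gene length in kilobases and by the library's total. The tables held 21652 genes, 21541 of which matched an Ensembl identifier in the reference names, and 495 had no symbol. Whether the protocol kept the strand is not stated, so overlapping genes on opposite strands were not told apart. Library totals of assigned counts were 27.7 to 39.8 M (M, 1e6) (iWAT, 22 °C), 27.3 to 36.5 (iWAT, 6 h), 30.7 to 38.3 (iWAT, 24 h), 25.3 to 36.7 (BAT, 22 °C), 30.1 to 41 (BAT, 6 h) and 25.7 to 39.7 (BAT, 24 h). Between 60 pairs of libraries of a group, chi-square per degree of freedom was 14.6 to 191, so the spread between libraries exceeded counting noise.

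Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with a minimum count of 10, scaled by TMM factors and tested by the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called. The 3 groups of a tissue shared a fit, and all 30 libraries of the 6 groups entered 1 fit where tissues were compared. The 9 comparisons were each cold group against 22 °C, 24 h against 6 h within each tissue, BAT against iWAT at 22 °C, and the difference of the cold response between tissues at 6 h and at 24 h. CPM used TMM-scaled library sizes. Errors of CPM are standard deviations and those of log2 fold changes approximate standard errors (size over the root of F).

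Gene lists numbered 34, written before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes, apart from alternatives and tests said below to have been chosen after seeing the data. Of these lists 33 had 5 or more tested members and were tested with limma 3.58.1 by camera with a preset correlation between genes of 0.01, again with a correlation estimated from the data, and by the rotation test fry. Trac, Ighm, Igkc and Eva1 had no match. Named genes were the 6 largest rises and 6 largest falls among called genes with no overlap between the libraries of the groups and a mean of at least 5 CPM in a group, leaving out predicted genes and clones, up to 4 called members of each list called by camera, and 14 genes fixed beforehand. The condition on overlap was not used for differences between tissues.

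Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 5 libraries, limma on log2 FPKM with pseudocounts of 1 and 0.1, fits of 2 groups or of all 30 libraries, and leaving out each library. The replicate number as a block was also tried. Covariates for skeletal muscle and for stromal lists were chosen after seeing the data. The calling was tested on simulated data with 200 changed genes and a further small set of shifted genes, which the called counts include. edgeR called 152 genes with 5 false in simulated iWAT and 151 with 2 false in simulated BAT, and recovered 73.1% and 81.8% of changes of log2 1. DESeq2 had 12.9% and 7.65% false calls. In each group of 5 libraries, a library was set apart when its gap to the nearest other, divided by the range, exceeded Dixon's value of 0.710. Splits of the libraries were drawn 100 times with a fixed seed of 11.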

Results

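Bulk RNA sequencing covered inguinal white adipose tissue (iWAT) and brown adipose tissue (BAT) of male C57BL/6J mice in 6 groups of 5 libraries. Each tissue was labelled as sampled at 22 °C, after 6 h at 6 °C and after 24 h at 6 °C, while the housing notes give a room of 24 ± 2 °C. The 30 libraries held 25.3 to 41 M assigned counts each (M, 1e6). Mitochondrially encoded genes took 12.4 ± 1.81% of counts (mean ± SD, n = 5) in iWAT at 22 °C, 14.2 ± 1.86% after 6 h and 13.5 ± 0.98% after 24 h. In BAT they took 26 ± 0.432%, 25.3 ± 2.41% and 24.6 ± 0.313%. The series asks what cold does to the transcriptomes of both depots. Nothing in the labels says that the replicates of a group are separate animals, or that libraries of the same number came from 1 mouse. All p-values therefore measure the spread between samples.

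After 6 h in the cold, iWAT held more mRNA of many genes of heat production, mitochondria and fuel use, and less of some genes of matrix, progenitor cells, vessels and macrophages. No list call of this comparison held with an estimated correlation (adjusted p = 0.168 to 0.483). Dio2 (ENSMUSG00000007682), whose enzyme activates thyroid hormone, rose from 23.5 ± 26.2 to 317 ± 244 CPM (counts per 1e6 assigned counts, mean ± SD, n = 5). Its log2 fold change was 3.76 ± 0.8 (± approximate SE, adjusted p = 0.0064 by edgeR's quasi-likelihood test). Ppargc1a (ENSMUSG00000029167), a coactivator that drives mitochondrial biogenesis, rose from 20.2 ± 5.82 to 116 ± 84.4 CPM (log2 2.52 ± 0.42, adjusted p = 0.0021). Other large rises had no overlap between the 5 cold and 5 control libraries. They were Mfsd2a (ENSMUSG00000028655), a lysophospholipid transporter (log2 3.32 ± 0.58), and Slc25a34, a mitochondrial carrier protein (3.19 ± 0.58). Ankrd9 (2.22 ± 0.46) and the cell cycle inhibitor Cdkn1a (2.1 ± 0.2) followed. The largest falls by the rule for naming genes were those of the alarmin cytokine Il33 (ENSMUSG00000024810; log2 -2.44 ± 0.41), the protease inhibitor Serpinb1a (-1.63 ± 0.29), and Glt8d2 (-1.51 ± 0.38). Next came Hacd4, an enzyme of fatty acid elongation (-1.42 ± 0.27), the sodium-calcium exchanger Slc8a1 (-1.4 ± 0.27) and the apelin receptor Aplnr (-1.39 ± 0.2).

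Among the thermogenic adipocyte genes, 13 of 25 tested rose and none fell (14 adjusted over the list alone), with a median log2 fold change of 1.14. They included Ppargc1b (1.63 ± 0.26) and Elovl3, an elongase of very long fatty acids (3.53 ± 0.86). Most genes of the respiratory chain and of the tricarboxylic acid cycle rose in iWAT. Of the nuclear-encoded respiratory chain genes 31 of 34 rose (34 adjusted over the list alone, median 0.62), with the electron carrier cytochrome c, Cycs, at 1.17 ± 0.25. In this list 22 °C replicate 4 (mean log2 CPM 8.05, others 7.09 to 7.3) stood above 6 h replicate 3 (7.51, others 8.09 to 8.27). Of the tricarboxylic acid cycle genes 15 of 17 rose (17 adjusted over the list alone, median 0.67), among them Idh3a (0.96 ± 0.19) and citrate synthase, Cs (0.66 ± 0.15). Mitochondrial biogenesis genes rose in 9 of 17 cases (10 adjusted over the list alone, median 0.38) and mitochondrially encoded genes in 3 of 13 (5 adjusted over the list alone, median 0.44). The camera test gave adjusted p = 7.47e-07, 5.33e-15, 2.83e-09, 1.01e-05 and 0.000427 for these 5 lists, and none held with an estimated correlation between genes (adjusted p = 0.415 to 0.42).

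Some genes of fuel use rose as well. Of the genes for fatty acid uptake and triglyceride synthesis 15 of 24 rose (17 adjusted over the list alone, median 0.52), with the acyltransferases Dgat1 (0.86 ± 0.12) and Agpat2 (1.02 ± 0.19). Of the genes for glucose uptake and glycolysis 15 of 22 rose (18, median 0.74), with Pgam1 (0.94 ± 0.17) and hexokinase Hk2 (0.74 ± 0.16). Fatty acid oxidation genes rose in 10 of 26 cases and fell in 1 (19 and 1 adjusted over the list alone, median 0.5). The faller was Cpt1a (-0.79 ± 0.18), whose enzyme lets long-chain fatty acids into mitochondria. Branched-chain amino acid catabolism (12 of 19 rose, 13 adjusted over the list alone, median 0.33) and de novo lipogenesis (4 of 22 rose, 7 adjusted over the list alone, median 0.57), with the lipogenic regulator Thrsp at 1.1 ± 0.24, also passed camera. Of the genes of lipolysis and beta-adrenergic signalling 7 of 19 rose and 1 fell (8 and 1 adjusted over the list alone). Their median was 0.2 (but -0.04 on deposited FPKM). In the listed order, camera's adjusted p values were 2.83e-09, 2.93e-08, 3.46e-06, 1.18e-06, 0.000519 and 0.00641. With an estimated correlation, adjusted p = 0.168 for fatty acid uptake and 0.415 to 0.42 for the others.

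Further rises came from glucocorticoid-responsive genes (5 of 16, 5 adjusted over the list alone, median 0.44), with Fkbp5 at 0.75 ± 0.19. They also came from the integrated stress response (4 of 20, 6 adjusted over the list alone, 0.39), with asparagine synthetase Asns at 0.62 ± 0.14, and from heat shock proteins (5 of 13, 6 adjusted over the list alone, 0.36). Their camera adjusted p values were 2.32e-05, 0.00972 and 0.00972, and adjusted p = 0.415, 0.415 and 0.479 with an estimated correlation (heat shock proteins 0.0895 by the rotation test fry). For cholesterol synthesis and uptake 5 of 20 rose (5 adjusted over the list alone, 0.36). Camera gave adjusted p = 0.00972, adjusted p = 0.483 with an estimated correlation, 0.109 by fry, 0.0514 without 22 °C replicate 4 and 0.0636 without 6 h replicate 4. Lists of other cell types were lower. Among adipose progenitor and fibroblast markers 5 of 17 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.68). Cd34 stood at -1.23 ± 0.27 and the riser F3, tissue factor, at 0.73 ± 0.14. Collagen and matrix genes fell in 7 of 21 cases (7 adjusted over the list alone, -0.43), with Col1a1 at -0.87 ± 0.22. Endothelial markers fell in 6 of 15 (8, -0.38), with Vwf at -0.94 ± 0.22. Macrophage markers fell in 6 of 16 (7, -0.62), with the mannose receptor Mrc1 at -0.99 ± 0.26. Camera's adjusted p values were 0.000394, 0.000519, 0.000815 and 0.000815, and adjusted p = 0.42 to 0.425 with an estimated correlation. Proliferation genes fell in 3 of 20 cases (3 adjusted over the list alone, -0.48, camera adjusted p = 0.00984, adjusted p = 0.45 with an estimated correlation, and 0.052 without 6 h replicate 3), with 6 h replicate 2 apart at a mean log2 CPM of 0.91 (others 0.12 to 0.28). Skeletal muscle markers fell in 7 of 10 cases (8 adjusted over the list alone, camera adjusted p = 0.0952). Their mean log2 CPM was 7.12 in 22 °C replicate 2 against -1.59 to -1.41 in the other 4 controls.

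Ucp1 (ENSMUSG00000031710), the uncoupling protein of brown-type fat cells, averaged 322 ± 354 CPM at 22 °C and 2620 ± 2200 after 6 h in iWAT (log2 3.03 ± 0.9, adjusted p = 0.025), with overlapping groups. Its adjusted p was 0.0557 without 22 °C replicate 1, 0.0643 without 22 °C replicate 2, 0.0552 without 6 h replicate 4 and 0.0625 without 6 h replicate 5. Pdk4, which restrains glucose oxidation, had log2 1.66 ± 0.5 (adjusted p = 0.027). Its adjusted p was 0.0534 to 0.076 without 22 °C replicate 1, 2 or 5 or 6 h replicate 4 or 5. The cold-inducible RNA-binding gene Rbm3 had 0.29 ± 0.09 (adjusted p = 0.027). Its adjusted p was 0.0531 to 0.0682 without 22 °C replicate 1, 2, 3 or 5 or 6 h replicate 2 or 5. Genes that did not pass were the hormone Fgf21 (2.67 ± 0.98, adjusted p = 0.056), the lipid droplet gene Cidea (0.98 ± 0.51, adjusted p = 0.17) and leptin, Lep (-0.16 ± 0.33). Nor did the lipogenic enzymes Fasn (0.6 ± 0.28) and Acly (0.86 ± 0.43), Nr4a1 (-0.02 ± 0.6), Per1 (0.3 ± 0.13) and Cirbp (0.06 ± 0.15). Over 13689 tested genes, 1769 rose and 1379 fell, 425 of them by a log2 of at least 1 in size. The count of 3148 genes dropped to 1525, 1585 and 1913 without 22 °C replicate 1, 22 °C replicate 2 and 6 h replicate 5. It was 1610 with the muscle list as a covariate and 4 with the mean of the endothelial, macrophage and progenitor lists as a covariate, both chosen after seeing the data. On deposited FPKM, where the median of all tested genes moved from -0.03 to -0.15 (pseudocount 1) or -0.25 (pseudocount 0.1), 575 or 582 rose and 4324 or 4201 fell. With upper-quartile factors 1250 rose and 2074 fell.

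**Figure D1:**
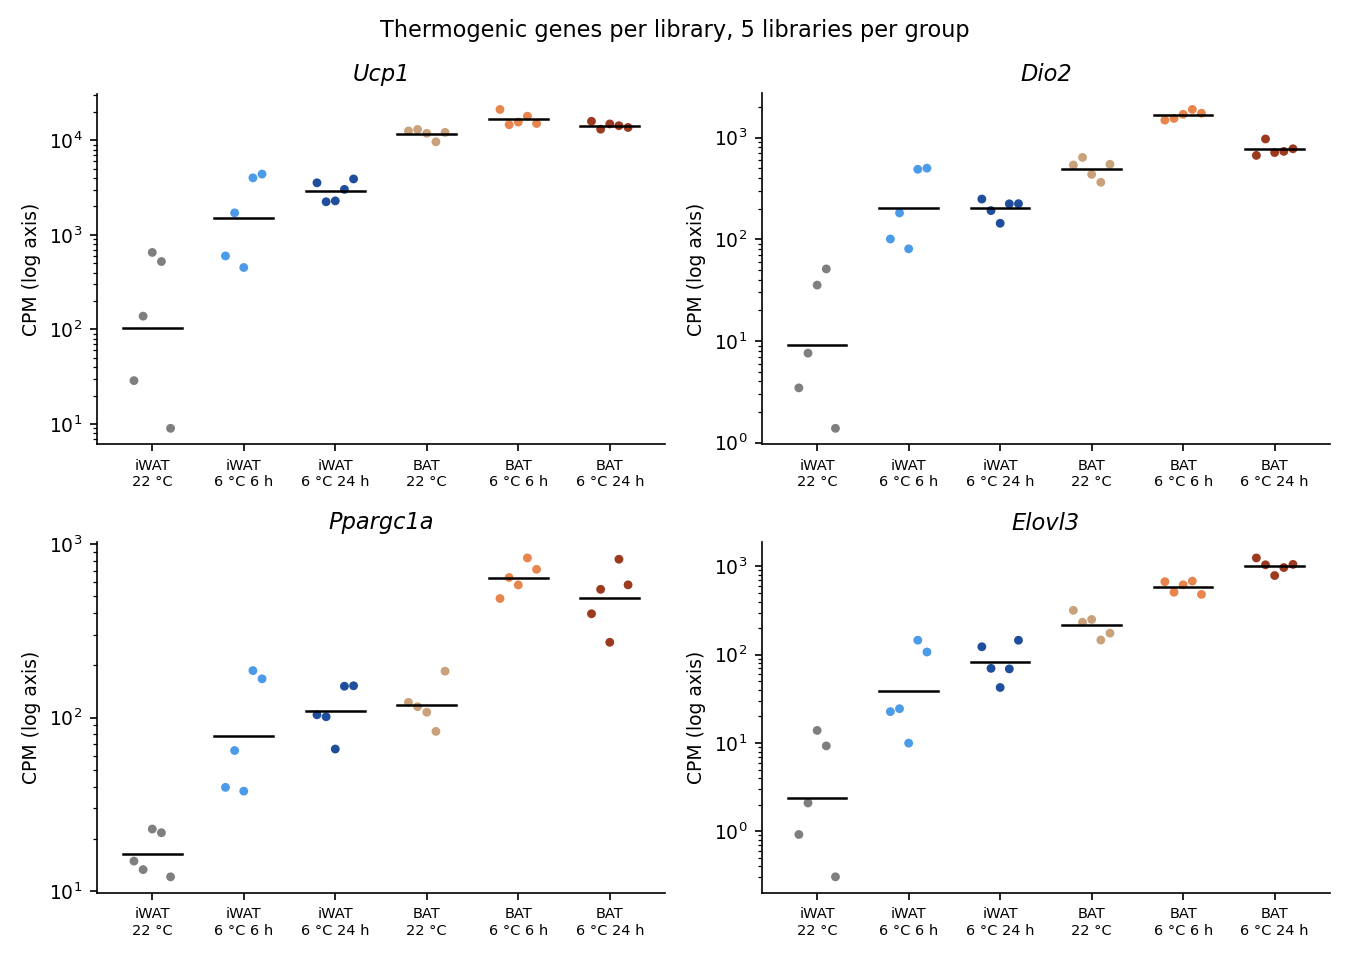
CPM (log axis, scaled over all 30 libraries) of Ucp1, Dio2, Ppargc1a and Elovl3 in each library of the 6 groups, with a bar at the geometric mean of 5 libraries. In iWAT, Ucp1 lay between 9.01 and 653 CPM at 22 °C and between 2240 and 3910 after 24 h, and in BAT at 22 °C between 9650 and 13000.

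After 24 h in the cold, iWAT held more mRNA of some lipid-handling and thermogenic genes than at 22 °C. Sgk2 (ENSMUSG00000017868), a kinase gene, rose from 0.157 ± 0.248 to 15.7 ± 4.35 CPM (log2 6.76 ± 1.09, adjusted p = 0.00099). Fabp3 (ENSMUSG00000028773), a carrier of fatty acids inside cells, rose from 18.3 ± 21.9 to 621 ± 257 CPM (log2 5.09 ± 1.11, adjusted p = 0.0049). The kininogen gene Kng2 (4.77 ± 0.84), Cend1 (4.82 ± 0.65), the R-spondin receptor Lgr6 (4.41 ± 1.12) and Elovl3 (4.08 ± 0.88) completed the 6 largest rises by the rule for naming genes. Ucp1 reached 3540 ± 874 CPM (log2 3.46 ± 0.91, adjusted p = 0.013), Dio2 243 ± 46.6 (3.37 ± 0.78) and Ppargc1a stood at log2 2.74 ± 0.43. The stress-induced hormone genes Fgf21 (ENSMUSG00000030827, 4.48 ± 0.98, adjusted p = 0.0051) and Gdf15 (ENSMUSG00000038508, 4.64 ± 0.85) rose, as did Pdk4 (2.24 ± 0.51) and Rbm3 (0.65 ± 0.09, adjusted p = 0.00046). The largest falls by that rule were Il33 (-2.34 ± 0.41), Aplnr (-1.99 ± 0.2) and the Wnt pathway regulators Dkk2 (-2.39 ± 0.54) and Sfrp2 (-2.07 ± 0.53). The estrogen sulfotransferase Sult1e1 (-2.14 ± 0.6; adjusted p = 0.0575 without 22 °C replicate 1) also fell. The muscle enolase Eno3 fell (-1.9 ± 0.6, adjusted p = 0.033), but its adjusted p was 0.181 without the muscle-rich 22 °C replicate 2 and 0.0581 to 0.0703 without 24 h replicate 1, 2, 4 or 5.

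Thermogenic genes rose in 18 of 25 cases in iWAT at 24 h (20 adjusted over the list alone, median 1.81), with the transcription factor Irf4 at 3.25 ± 0.55. Rises also covered 27 of 34 respiratory chain genes (34 adjusted over the list alone, 0.66), 15 of 17 of the tricarboxylic acid cycle (16, 0.75) and 13 of 17 of mitochondrial biogenesis (13, 0.52). In the respiratory chain list the control replicate 4 stood apart at a mean log2 CPM of 8.05 (others 7.09 to 7.3). They covered 13 of 26 of fatty acid oxidation (21, 0.51), 16 of 24 of fatty acid uptake and triglyceride synthesis (18, 0.52) and 14 of 22 of glucose uptake and glycolysis (17, 0.79). Camera's adjusted p values were 2.26e-13, 1.73e-15, 2.22e-10, 6.67e-08, 3.35e-09, 3.43e-09 and 2.01e-09 in that order, and adjusted p = 0.16 to 0.354 with an estimated correlation. The integrated stress response rose in 8 of 20 cases and fell in 2 (13 and 2 adjusted over the list alone, 0.49), with Mthfd2 of mitochondrial folate metabolism at 2.11 ± 0.26. Heat shock proteins rose in 6 of 13 (6, 0.44), with the chaperone Hspa8 at 1.08 ± 0.2, and glucocorticoid-responsive genes in 6 of 16 (6, 0.41). Their camera adjusted p values were 0.000124, 0.000124 and 0.000516, and adjusted p = 0.16, 0.466 and 0.354 with an estimated correlation. Immediate early and cAMP-responsive genes rose in 6 of 24 cases and fell in 1 (7 and 1 adjusted over the list alone, median 0.36), with the nuclear receptor Nr4a3 at 2.71 ± 0.56. Their camera test gave adjusted p = 0.0294, adjusted p = 0.631 with an estimated correlation, 0.113 by fry, 0.0617 without 22 °C replicate 5 and 0.148 without 24 h replicate 5.

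Matrix genes fell in 9 of 21 cases in iWAT at 24 h (12 adjusted over the list alone, -0.5), with Col1a1 at -1.01 ± 0.22, and progenitor markers in 3 of 17 (3, -0.6), with Cd34 at -1.38 ± 0.27. Camera gave adjusted p = 0.000219 and 0.000746, and adjusted p = 0.483 and 0.501 with an estimated correlation. Endothelial markers fell in 6 of 15 cases (6 adjusted over the list alone, -0.22). They had adjusted p = 0.0244 by camera, adjusted p = 0.631 with an estimated correlation, 0.116 by fry, 0.0821 without 22 °C replicate 5 and 0.0514 without 24 h replicate 1. Macrophage markers were not called (1 of 16 fell; -0.44, adjusted p = 0.122). Lipolysis and beta-adrenergic signalling (median 0.14, but -0.01 on FPKM with pseudocount 1; adjusted p = 0.0398), mitochondrially encoded genes (0.23; 0.0284) and proliferation (-0.34; 0.0398) passed camera but not with an estimated correlation (adjusted p = 0.509, 0.631 and 0.631), and the latter 2 not by fry (0.116 and 0.0762). The first lost its call without 22 °C replicate 1 or 2 or 24 h replicate 5 (0.0575 to 0.0896). The second lost it without 22 °C replicate 2 or 5 or 24 h replicate 4 (0.0561 to 0.0772) and the third without 22 °C replicate 1 or 24 h replicate 2, 3 or 5 (0.0563 to 0.142). De novo lipogenesis was not called (2 of 22 rose; 0.23, adjusted p = 0.122), nor were branched-chain amino acid catabolism (3 of 19 rose; 0.1, adjusted p = 0.12) and cholesterol synthesis and uptake (4 of 20 rose and 1 fell; 0.21, adjusted p = 0.12).

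Leptin mRNA, Lep (ENSMUSG00000059201), fell in iWAT at 24 h (log2 -1.1 ± 0.34, adjusted p = 0.029), though its adjusted p was 0.0567 to 0.0738 without 22 °C replicate 1 or 5 or 24 h replicate 1, 2, 3 or 4. Per1, a clock gene, rose (0.48 ± 0.13, adjusted p = 0.016, but 0.0675 and 0.0681 on FPKM). Cidea (1.38 ± 0.51, adjusted p = 0.063), Fasn (0.28 ± 0.28), Acly (0.53 ± 0.43), Nr4a1 (0.12 ± 0.6) and Cirbp (0.01 ± 0.15) did not pass. In all, 1757 genes rose and 1388 fell, 520 of them by a log2 of at least 1 in size. The 3145 calls became 2053 without 22 °C replicate 1 and 381 with the covariate of endothelial, macrophage and progenitor lists, chosen after seeing the data. On FPKM 1035 or 1017 rose and 3128 or 2864 fell while the median of all tested genes moved from -0.04 to -0.12 or -0.19. Upper-quartile factors gave 1381 rises and 1891 falls.

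**Figure D2:**
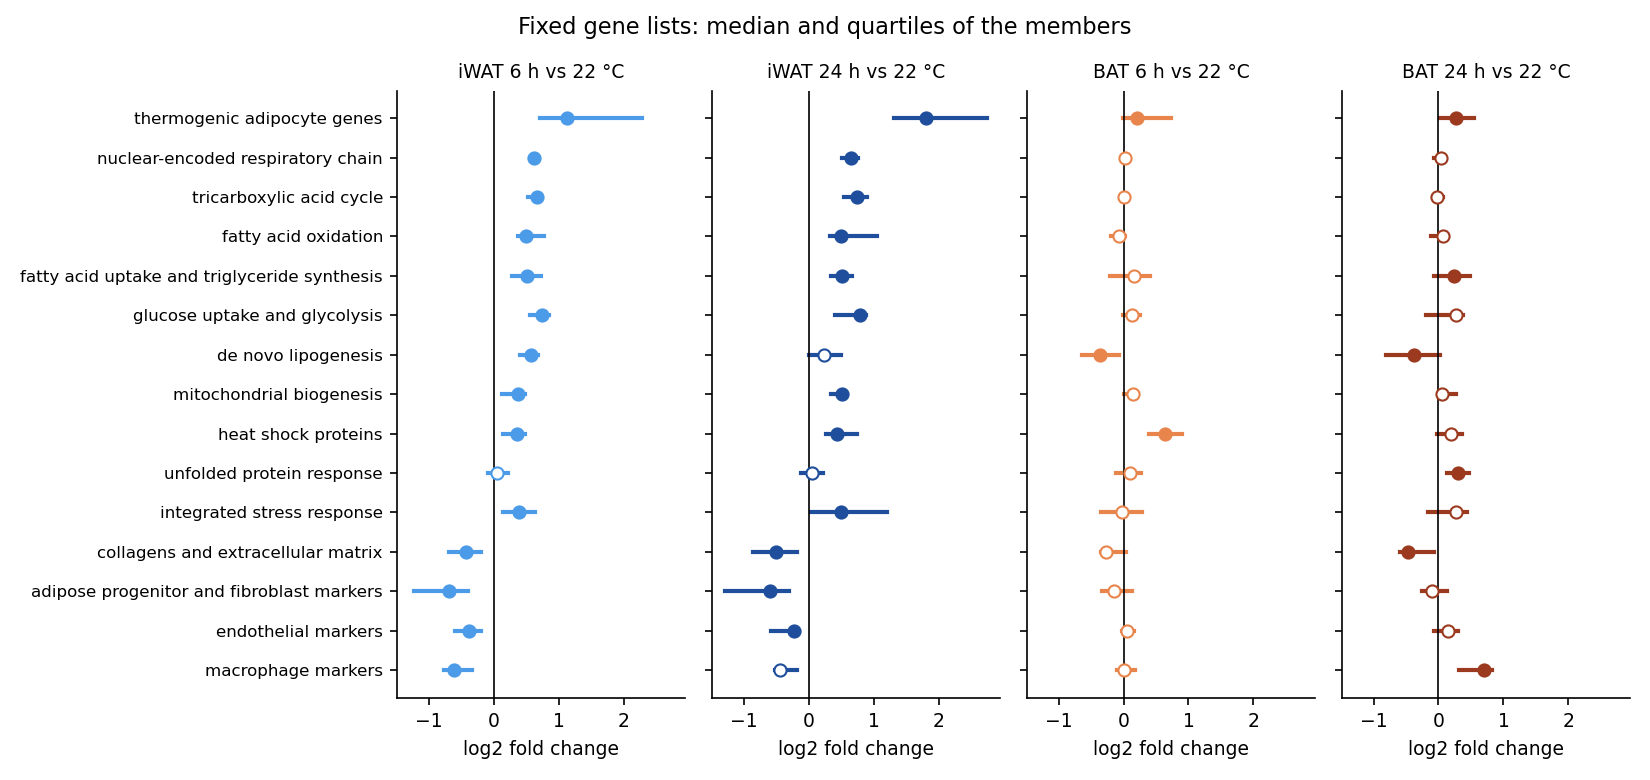
Median log2 fold change of the tested members of 15 gene lists (points; lines span the quartiles) in each cold group against 22 °C of the same tissue; filled points have a camera adjusted p under 0.05. The respiratory chain list stood at 0.62 and 0.66 in iWAT and at 0.03 and 0.05 in BAT after 6 h and 24 h.

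Between 6 h and 24 h in the cold, 1 of 13689 iWAT genes differed by edgeR's test. Wdr6 (ENSMUSG00000066357), which codes for a WD-repeat protein, fell from 30.9 ± 3.93 to 19.1 ± 2.01 CPM (log2 -0.69 ± 0.1, adjusted p = 0.031). That call was lost without 6 h replicate 2 (adjusted p = 0.107), 6 h replicate 3 (0.135), 24 h replicate 2 (0.0879), 24 h replicate 4 (0.173) or 24 h replicate 5 (0.136). It was also lost with the replicate number as a block (0.153). At an unadjusted p under 0.05 there were 1351 genes, and DESeq2 called 122. Leaving out 1 library gave 0 to 13 genes, with 13 without 6 h replicate 4, 6 without 24 h replicate 1 and 2 without 6 h replicate 5. Against 6 h, the 24 h values of the fixed genes had wide errors in iWAT and did not pass. The log2 values were Ucp1 0.44 ± 0.83, Dio2 -0.38 ± 0.71, Elovl3 0.54 ± 0.77, Ppargc1a 0.22 ± 0.4, Cidea 0.4 ± 0.51, and Fgf21 1.8 ± 0.83. Further values were Lep -0.94 ± 0.34, Fasn -0.32 ± 0.28, Acly -0.32 ± 0.43, Pdk4 0.58 ± 0.49, Nr4a1 0.14 ± 0.6, Per1 0.18 ± 0.13, Cirbp -0.06 ± 0.15 and Rbm3 0.36 ± 0.09. Camera placed the thermogenic (median 0.4, adjusted p = 9.18e-06), immediate early (0.34, 0.000207) and creatine and calcium cycling genes (0.26, 0.00133) higher at 24 h. It placed branched-chain amino acid catabolism lower (-0.25, 6.71e-08; 8 members lower adjusted over the list alone). With an estimated correlation, adjusted p = 0.926, 0.672, 0.25 and 0.527, and with fry 0.737, 0.518, 0.0843 and 0.222. Camera calls lost without 1 library were de novo lipogenesis (-0.27, adjusted p = 0.004; 0.352 without 6 h replicate 4 and 0.131 without 24 h replicate 3) and macrophage markers (0.28, 0.00609; 0.22 without 6 h replicate 4). So were the integrated stress response (0.13, 0.0156; 0.0514 without 6 h replicate 2 and 0.128 without 24 h replicate 5) and heat shock proteins (0.17, 0.0228; 0.208, 0.14 and 0.109 without 6 h replicate 3, 24 h replicate 1 and 24 h replicate 5). Fatty acid oxidation was lost too (0.08, 0.0228; 0.0972, 0.506, 0.138 and 0.122 without 6 h replicate 1, 6 h replicate 3, 24 h replicate 1 and 24 h replicate 5). With an estimated correlation these 5 had adjusted p = 0.926, except the integrated stress response with adjusted p = 0.527, and fry gave 0.303 to 0.849. Of the 3148 genes called at 6 h, none moved back or further by 24 h in edgeR's test, against 35 and 9 of 3972 by DESeq2. A further 1125 genes were called at 24 h and not at 6 h, of which 1 also differed between 6 h and 24 h.

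In BAT, 6 h of cold raised mRNA of 9 of 13 heat shock proteins and 10 of 23 thermogenic genes and lowered that of 9 of 22 lipogenic genes, list calls that did not hold with an estimated correlation (adjusted p = 0.251 to 0.704). Dio2 rose from 430 ± 93.3 to 1410 ± 136 CPM (log2 1.71 ± 0.14, adjusted p = 1e-06) and Ppargc1a from 105 ± 32.6 to 548 ± 111 CPM (2.39 ± 0.27, adjusted p = 1.5e-05). Ucp1, already abundant, went from 10100 ± 1150 to 14300 ± 2260 CPM (0.5 ± 0.1, adjusted p = 0.0017; 0.635 in the fit over all 30 libraries). The largest rises by the rule for naming genes were the acyl-CoA thioesterase Acot5 (ENSMUSG00000042540; log2 4.66 ± 0.46), the ketone body enzyme Bdh1 (ENSMUSG00000046598, 4.03 ± 0.49) and the cytochrome P450 Cyp2b10 (ENSMUSG00000030483, 3.92 ± 0.98). Next were the tight junction gene Cldn1 (2.76 ± 0.24), the cell cycle transcription factor E2f2 (2.75 ± 0.22) and the clock transcription factor Bmal1 (2.44 ± 0.28). The largest falls by that rule were the lactate receptor Hcar1 (ENSMUSG00000049241, -2.67 ± 0.32), the phosphoinositide 3-kinase subunit Pik3r1 (ENSMUSG00000041417, -2.08 ± 0.26) and the matrix gene Svep1 (-1.99 ± 0.25). The neurotrophin receptor Ntrk3 (-1.75 ± 0.19), Igfals, which binds insulin-like growth factor complexes (-1.72 ± 0.23), and Tmem179 (-1.67 ± 0.2) followed.

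Thermogenic genes rose in 10 of 23 cases in BAT at 6 h (10 adjusted over the list alone, median 0.21), with Elovl3 at 1.38 ± 0.18. By camera the list had adjusted p = 6.11e-06, and adjusted p = 0.251 with an estimated correlation. In this list 22 °C replicate 4 stood apart at a mean log2 CPM of 5.77 (others 6.07 to 6.18). Heat shock proteins rose in 9 of 13 cases (10 adjusted over the list alone, 0.64, camera adjusted p = 9.55e-09, and adjusted p = 0.309 with an estimated correlation). Hsp90aa1 (ENSMUSG00000021270) went from 392 ± 91.1 to 1230 ± 113 CPM (1.65 ± 0.14, adjusted p = 1.3e-06) and Hspa8 stood at 1 ± 0.12. Immediate early and cAMP-responsive genes rose in 7 of 24 cases and fell in 2 (8 and 2 adjusted over the list alone, 0.21), with Nr4a3 (ENSMUSG00000028341) at 1.81 ± 0.14 and the phosphatase Dusp1 at 1.22 ± 0.12. Glucocorticoid-responsive genes rose in 7 of 16 (8, 0.45), with the transcription factor Zbtb16 at 1.89 ± 0.44. Camera's adjusted p values were 0.0024 and 2.27e-05, and adjusted p = 0.441 and 0.25 with an estimated correlation. De novo lipogenesis genes fell in 9 of 22 cases (10 fell and 1 rose adjusted over the list alone, -0.36, camera adjusted p = 0.00189, and adjusted p = 0.704 with an estimated correlation). Thrsp stood at -1.13 ± 0.16, Srebf1, a transcription factor of lipid synthesis, at -0.67 ± 0.13 and Acly (ENSMUSG00000020917), which makes cytosolic acetyl-CoA, at -1.16 ± 0.29. Fasn (ENSMUSG00000025153), the fatty acid synthase, fell from 12000 ± 2290 to 7300 ± 1620 CPM (-0.72 ± 0.22, adjusted p = 0.023). Its adjusted p was 0.06, 0.0511 and 0.0551 without 22 °C replicate 1, 22 °C replicate 3 and 6 h replicate 5. The respiratory chain (1 of 34 rose; median 0.03, camera adjusted p = 0.819) and tricarboxylic acid cycle lists (1 of 17 rose; 0.01, 0.852) were not called.

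Skeletal muscle markers passed camera in BAT at 6 h (3 of 15 fell, 4 adjusted over the list alone, median -2.94). Their adjusted p was 0.00129 (adjusted p = 0.774 with an estimated correlation, 0.115 by fry and 0.811 with the muscle list itself as a covariate). Myl1, a muscle myosin light chain, had -1.77 ± 0.51, with adjusted p = 0.0623 without 22 °C replicate 5. The mean log2 CPM of the muscle markers per library ranged from 3.87 to 8.91 at 22 °C, from 0.13 to 6.17 at 6 h and from -1.57 to 7.89 at 24 h. Nr4a1 (ENSMUSG00000023034), an immediate early nuclear receptor, had -1.06 ± 0.35 (adjusted p = 0.038). Its adjusted p was 0.06 to 0.0906 without 22 °C replicate 2, 3 or 4 or 6 h replicate 1, 2 or 4. Lep (-1.15 ± 0.43, adjusted p = 0.063), Fgf21 (0.78 ± 0.5), Cidea (-0.04 ± 0.09), Pdk4 (0.06 ± 0.13), Per1 (0.05 ± 0.12), Cirbp (-0.28 ± 0.15) and Rbm3 (0.08 ± 0.1) did not pass. In all, 1634 of 13090 tested BAT genes rose and 1333 fell, 438 of them by a log2 of at least 1 in size. The muscle covariate, chosen after seeing the data, left 2190 called, 1998 of them among the 2967. On FPKM the split was 1286 or 1298 rises and 1581 or 1584 falls.

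**Figure D3:**
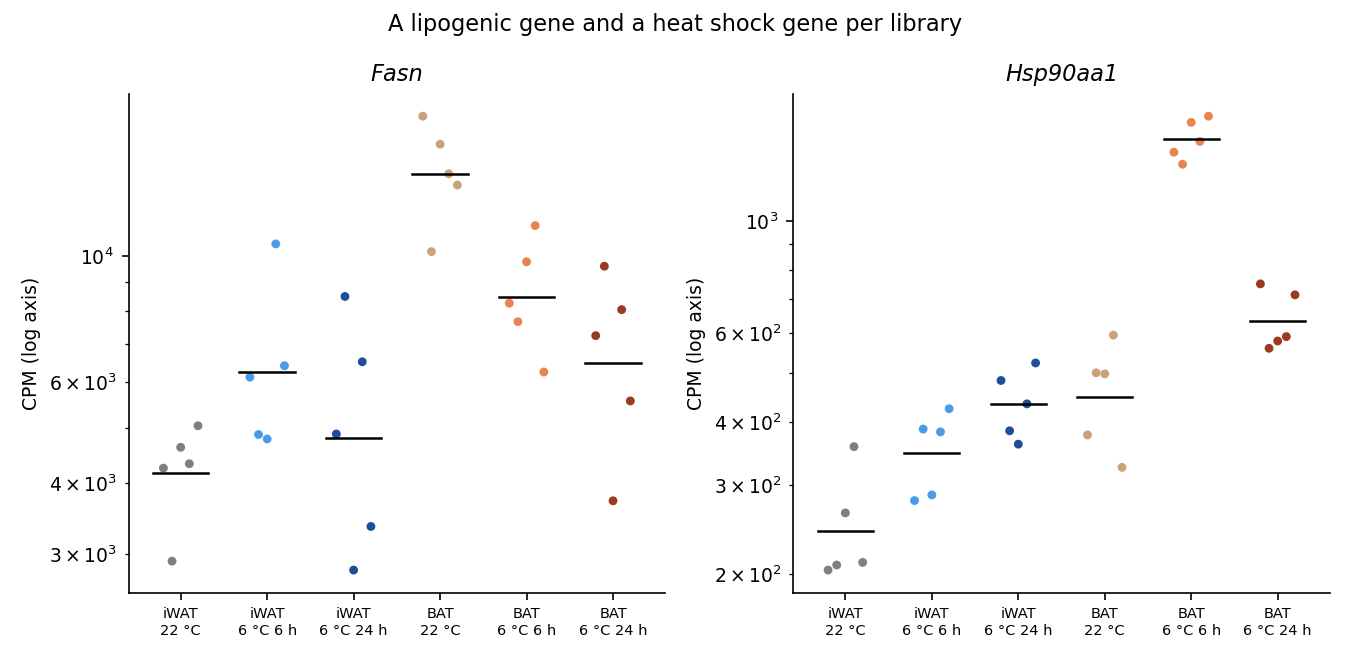
CPM (log axis, scaled over all 30 libraries) of Fasn and Hsp90aa1 in each library of the 6 groups, with a bar at the geometric mean of 5 libraries. In BAT, Hsp90aa1 rose by 1.65 on the log2 scale at 6 h and then fell by 1.19, while Fasn fell by 0.72 and, against 22 °C, by 1.06 at 24 h.

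After 24 h in the cold, BAT had gained mRNA of 11 of 23 thermogenic genes against 22 °C and lost mRNA of 12 of 22 lipogenic genes, list calls that did not hold with an estimated correlation (adjusted p = 0.154 and 0.433). Ckb (ENSMUSG00000001270), the brain-type creatine kinase, rose from 26.7 ± 6.89 to 384 ± 92.7 CPM (log2 3.85 ± 0.2, adjusted p = 1e-08). Bmp8b (ENSMUSG00000002384), a secreted factor of brown fat, rose by 4.93 ± 0.4. Bdh1 (5.37 ± 0.5), Cyp2b10 (4.97 ± 1.02), the potassium channel gene Kcnh6 (4.78 ± 0.49), Cpne5, a calcium-dependent membrane-binding protein (ENSMUSG00000024008, 4.28 ± 0.37), and Acot5 (3.99 ± 0.46) were the other large rises without overlap. The largest falls by the rule for naming genes were Ntrk3 (-2.6 ± 0.19), Hcar1 (-2.34 ± 0.31), Pik3r1 (-2.3 ± 0.27), the fructose transporter Slc2a5 (-2.23 ± 0.4), Nr4a1 (-2.17 ± 0.36) and Lctl (-1.92 ± 0.19).

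Thermogenic genes rose in 11 of 23 cases in BAT at 24 h (12 adjusted over the list alone, median 0.26), with Elovl3 at 2.17 ± 0.18, Ppargc1a at 2.08 ± 0.26 and Cidea at 0.45 ± 0.09, against controls of which replicate 4 stood apart (5.77, others 6.07 to 6.18). Genes of the unfolded protein response rose in 11 of 18 cases and fell in 3 (11 and 3 adjusted over the list alone, 0.31), with the chaperones Hspa5 (0.5 ± 0.05) and Sdf2l1 (2.21 ± 0.24). Fatty acid uptake and triglyceride synthesis genes rose in 12 of 24 cases and fell in 1 (14 and 1, 0.24), with Fabp3 at 1.37 ± 0.12. Glucocorticoid-responsive genes rose in 5 of 16 (5, 0.36), with Fkbp5 at 1.58 ± 0.25. Creatine and calcium cycling genes rose in 3 of 11 (3; median 0.003), with Alpl, a phosphatase that can act on phosphocreatine, at 1.87 ± 0.14 beside Ckb. De novo lipogenesis genes fell in 12 of 22 cases (12, -0.38), with Fasn at 5780 ± 1960 CPM (-1.06 ± 0.22), Acly at -1.24 ± 0.29 and the citrate carrier Slc25a1 at -1.58 ± 0.22. Matrix genes fell in 8 of 21 and rose in 2 (10 and 2, -0.47), with laminin Lama4 at -1 ± 0.08 and the basement membrane collagen Col4a2 at 0.82 ± 0.11. In the listed order, camera's adjusted p values were 2.88e-05, 2.88e-05, 0.000224, 0.000802, 0.00901, 5.64e-05 and 0.00844. These became adjusted p = 0.154, 0.143, 0.143, 0.17, 0.143, 0.433 and 0.778 with an estimated correlation. Branched-chain amino acid catabolism fell in 10 of 19 cases and rose in 3 (12 and 3, -0.21). Camera gave adjusted p = 0.0273 (adjusted p = 0.787 with an estimated correlation, and 0.0666, 0.101 and 0.0764 without 22 °C replicate 2, 24 h replicate 4 and 24 h replicate 5).

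Interferon-stimulated genes rose in 4 of 18 cases in BAT at 24 h (4 adjusted over the list alone, median 0.85, camera adjusted p = 0.0273, adjusted p = 0.792 with an estimated correlation, and 0.247 by fry). Without 24 h replicate 4, whose mean level of the list was 4.81 against 2.68 to 3.05 log2 CPM in the other 4, adjusted p was 0.707, and 0.0545 without 22 °C replicate 5. Macrophage markers rose in 3 of 16 cases and fell in 1 (5 and 1, 0.7, camera adjusted p = 0.027, adjusted p = 0.792 with an estimated correlation, 0.0969 by fry, and 0.104 and 0.0545 without those 2 libraries). In this list 22 °C replicate 4 stood apart at 3.26 (others 2.43 to 2.6). Skeletal muscle markers had a median of -1.51 with no member called. Camera's adjusted p was 0.0144 (adjusted p = 0.792 with an estimated correlation, 0.225 by fry, 0.0652 without 22 °C replicate 5, and 0.0542 and 0.0756 without 24 h replicates 1 and 2). Dio2 stood at 651 ± 105 CPM (log2 0.6 ± 0.14, adjusted p = 0.0042; 0.483 in the fit over all 30 libraries). Fgf21 rose (1.84 ± 0.5, adjusted p = 0.013, 0.0892 in that fit) and Lep fell (-1.72 ± 0.44, adjusted p = 0.0087). Ucp1 (12100 ± 795 CPM, 0.26 ± 0.1, adjusted p = 0.067), Pdk4 (0.36 ± 0.13), Per1 (-0.01 ± 0.12), Cirbp (-0.14 ± 0.15) and Rbm3 (0.08 ± 0.1) did not pass. Immediate early genes went both ways, with 5 of 24 higher and 5 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.992). In all, 1670 genes rose and 1360 fell, 440 of them by a log2 of at least 1 in size. The muscle covariate left 2403 called, 2195 of them among the 3030.

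From 6 h to 24 h, BAT lost mRNA of 7 of 13 heat shock proteins and 8 of 24 immediate early genes, list calls that did not hold with an estimated correlation (adjusted p = 0.369 and 0.318). Nr4a3 fell by 2.37 ± 0.14 on the log2 scale (adjusted p = 8.2e-08). Hsp90aa1 had -1.19 ± 0.14 and Dio2 -1.11 ± 0.14 (adjusted p = 0.00013; 0.216 in the fit over all 30 libraries). The largest rises by the rule for naming genes were Cpne5 (2.33 ± 0.33), the prostaglandin D synthase Ptgds (ENSMUSG00000015090, 2.04 ± 0.23), Bmp8b (2 ± 0.33), Ckb (1.64 ± 0.18), the lipid-binding gene Apod (1.56 ± 0.36) and Nradd (1.52 ± 0.16). The largest falls after Nr4a3 by that rule were Cldn1 (-1.69 ± 0.23), collagen Col7a1 (-1.61 ± 0.19), Lctl (-1.59 ± 0.19), Vat1l (-1.57 ± 0.21) and the acyl-CoA synthetase Acsm3 (-1.56 ± 0.21).

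Heat shock proteins fell in 7 of 13 cases in BAT from 6 h to 24 h (8 adjusted over the list alone, median -0.52, camera adjusted p = 3.79e-07, and adjusted p = 0.369 with an estimated correlation). Immediate early genes fell in 8 of 24 (8, -0.21, 0.000205, and adjusted p = 0.318 with an estimated correlation). Genes of the unfolded protein response rose in 7 of 18 cases (7 rose and 1 fell adjusted over the list alone, 0.16, camera adjusted p = 0.000816, and adjusted p = 0.318 with an estimated correlation), with Herpud1 at 0.62 ± 0.08. Interferon-stimulated genes rose in 5 of 18 (16 adjusted over the list alone, 0.99, 8.02e-05, adjusted p = 0.68 with an estimated correlation, and 0.183 by fry), with Isg15 at 1.47 ± 0.38. In this list 24 h replicate 4 stood apart. Weaker calls were cholesterol synthesis and uptake (5 of 20 fell; -0.22, adjusted p = 0.0171), macrophage markers (2 of 16 rose; 0.45, 0.014), fatty acid oxidation (7 of 26 rose and 1 fell; 0.1, 0.0277) and proliferation (3 of 13 rose; 0.37, 0.0277). Others were creatine and calcium cycling (2 of 11 rose; 0.98, 0.0284), fatty acid uptake (7 of 24 rose; 0.07, 0.0314), lipolysis (3 of 19 rose and 2 fell; 0.13, 0.0487) and lymphocyte markers (1 of 10 rose; 0.85, 0.0487). The creatine median included muscle genes that were not called, Ckmt2 (2.51 ± 1.27), Atp2a1 (1.46 ± 1.4) and Ryr1 (1.12 ± 1.21), chosen after their values were seen, and skeletal muscle markers had a median of 1.49 with none called. With an estimated correlation they had adjusted p = 0.908, 0.73, 0.68, 0.483, 0.318, 0.483, 0.607 and 0.605. By fry cholesterol had 0.343, macrophage markers 0.183 and lymphocyte markers 0.0542. Adjusted over the list alone 10, 3, 8 and 2, 3, 2, 8 and 2, 6 and 2, and 1 members were called. Each was lost without single libraries. Cholesterol lost its call without 6 h replicate 1 or 4 or 24 h replicate 3 (0.0677 to 0.213), macrophage without 24 h replicate 4 (0.0734) and oxidation without 24 h replicate 3 (0.0861). Proliferation lost it without 6 h replicate 1 or 2 or 24 h replicate 4 (0.056 to 0.0766), creatine without 6 h replicate 1 (0.0933), and uptake without 6 h replicate 1, 2 or 5 or 24 h replicate 3 (0.0518 to 0.0854). Lipolysis lost it without 6 h replicate 1, 2, 3 or 5 or 24 h replicate 1 or 4 (0.0565 to 0.16), and lymphocyte markers without 6 h replicate 1, 2 or 5 or 24 h replicate 1, 3 or 4 (0.0595 to 0.245).

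Elovl3 (0.78 ± 0.17) and Cidea (0.49 ± 0.09) rose from 6 h to 24 h in BAT, though not in the fit over all 30 libraries (adjusted p = 0.451 and 0.466). Nr4a1 had -1.12 ± 0.35 (adjusted p = 0.047). Its adjusted p was 0.0539 to 0.156 without 6 h replicate 3 or 5 or 24 h replicate 1, 2, 3 or 4. Ucp1 (-0.24 ± 0.1, adjusted p = 0.13), Ppargc1a (-0.31 ± 0.25), Fgf21 (1.06 ± 0.47), Lep (-0.58 ± 0.43), Fasn (-0.34 ± 0.21), Acly (-0.08 ± 0.29), Pdk4 (0.29 ± 0.13), Per1 (-0.07 ± 0.12), Cirbp (0.14 ± 0.15) and Rbm3 (0 ± 0.1) did not pass. Of 13090 BAT genes, 864 rose and 844 fell, with 1030 and 701 under upper-quartile factors and 1143 or 1140 and 524 or 513 on FPKM. Of the 2967 BAT genes called at 6 h, 654 had moved back toward the 22 °C level by 24 h and 111 had moved further the same way by the 24 h to 6 h test. Both tests share the 6 h libraries, whose noise favours moving back over moving further. How uneven these counts would be without a change from 6 h to 24 h was not tested. Another 1482 were called at 24 h and not at 6 h, of which 553 differed between 6 h and 24 h.

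At 22 °C the tissues differed in most genes. BAT exceeded iWAT in Ucp1 (log2 5.45 ± 0.77, adjusted p = 5e-07), Elovl3 (5.41 ± 0.74), Dio2 (4.67 ± 0.65), Cidea (3.43 ± 0.43), Pdk4 (3.34 ± 0.42), Ppargc1a (2.85 ± 0.38), Acly (1.94 ± 0.41), Fasn (1.74 ± 0.27) and Nr4a1 (3.57 ± 0.57). It was lower in Lep (-4.37 ± 0.46), Cirbp (-1.16 ± 0.16) and Rbm3 (-0.85 ± 0.1). Zic1, a transcription factor of dorsal mesoderm and brown fat, averaged 18.5 ± 7.62 CPM in BAT and had 2 counts in all 5 iWAT libraries together. The other genes with the largest BAT excess by the rule for naming genes were Lgr6 (9.22 ± 0.87), Kng2 (8.3 ± 0.7), the carbonic anhydrase Car14 (7.42 ± 0.5), Sgk2 (7.23 ± 0.83) and the muscle gene Myl2 (7.62 ± 1.78; adjusted p = 0.165 with the muscle covariate). The genes with the largest iWAT excess by the rule for naming genes included the position genes Hoxc10, Hoxa10 and Hoxc9. Position genes as a group were not tested. Hoxc10 averaged 17.3 ± 2.39 CPM in iWAT with no count in 5 BAT libraries. Hoxa10 averaged 11.2 ± 1.92 CPM against 1 count, and Hoxc9 9.47 ± 0.663 CPM against 10 counts. Albumin, Alb (-8.18 ± 0.42), the complement gene C6 (-6.91 ± 0.76) and Ugt8a (-6.26 ± 0.87) were also lower in BAT.

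White adipocyte-enriched genes were lower in BAT for 14 of 15 members and higher for 1 (14 and 1 adjusted over the list alone, median -3.17). The call held with an estimated correlation (camera adjusted p = 3.23e-11, and adjusted p = 0.0213 with an estimated correlation). All 34 respiratory chain genes (median 1.88), all 17 of the tricarboxylic acid cycle (2.18) and all 13 mitochondrially encoded genes (1.95) were higher in BAT. So were 23 of 26 for fatty acid oxidation with 2 lower (1.77), 21 of 23 for glycolysis (2.06) and 20 of 26 thermogenic genes with 2 lower (3.03). Adjusted over the list alone, these counts were 34, 17, 13, 23 and 2, 21, and 21 and 2. Camera's adjusted p values were 8.32e-25, 7.59e-23, 3.24e-09, 8.96e-12, 8.05e-13 and 2.21e-07, and adjusted p = 0.0623 to 0.253 with an estimated correlation. Brown adipocyte identity genes were higher in 10 of 13 cases and lower in 1 (11 and 1 adjusted over the list alone, 1.85, camera adjusted p = 1.9e-05, and adjusted p = 0.0623 with an estimated correlation). Matrix genes (19 of 21; -1.74), progenitor markers (16 of 17; -1.65) and macrophage markers (16 of 16; -1.92) were lower in BAT, with Col5a2 at -2.43 ± 0.12 and Mrc1 at -2.11 ± 0.25. Camera gave adjusted p = 3.12e-09, 3.28e-05 and 0.000214, and adjusted p = 0.118, 0.248 and 0.325 with an estimated correlation. Heat shock proteins were higher in 12 of 13 cases (1.22, adjusted p = 0.00199, and adjusted p = 0.374 with an estimated correlation). Camera also placed mitochondrial biogenesis (median 1.06, adjusted p = 1.28e-07), branched-chain amino acid catabolism (0.83, 8.15e-06), fatty acid uptake (0.6, 0.00581) and immediate early genes (0.75, 0.0152) higher in BAT. Interferon-stimulated (-1.35, 0.00343) and proliferation genes (-1.27, 0.0152) were lower. These 6 had adjusted p = 0.095, 0.248, 0.289, 0.374, 0.55 and 0.364 with an estimated correlation. De novo lipogenesis (0.92, 0.0321) and cholesterol genes (0.68, 0.0438) were higher in BAT, with adjusted p = 0.55 and 0.649 with an estimated correlation. The first had 0.0516 and 0.0531 without iWAT replicates 2 and 4, and the second 0.0503 to 0.0837 without iWAT replicate 2 or 4 or BAT replicate 1, 3 or 5. Fgf21 (2.11 ± 0.86, adjusted p = 0.031) had 0.0539 to 0.122 without 22 °C iWAT replicate 1, 4 or 5 or BAT replicate 1 or 4. Per1 (0.3 ± 0.13, adjusted p = 0.037) had 0.0583 to 0.123 without iWAT replicate 1, 2, 3 or 4 or BAT replicate 1, 4 or 5 and turned to -0.26 or -0.28 on FPKM. Of 14089 tested genes 4570 were higher and 4857 lower in BAT. With upper-quartile factors the counts were 3516 and 6254 and the median of all genes moved from -0.04 to -0.23. On FPKM they were 1966 or 1999 and 9302 or 9288 with a median of -0.34 or -0.58.

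**Figure D4:**
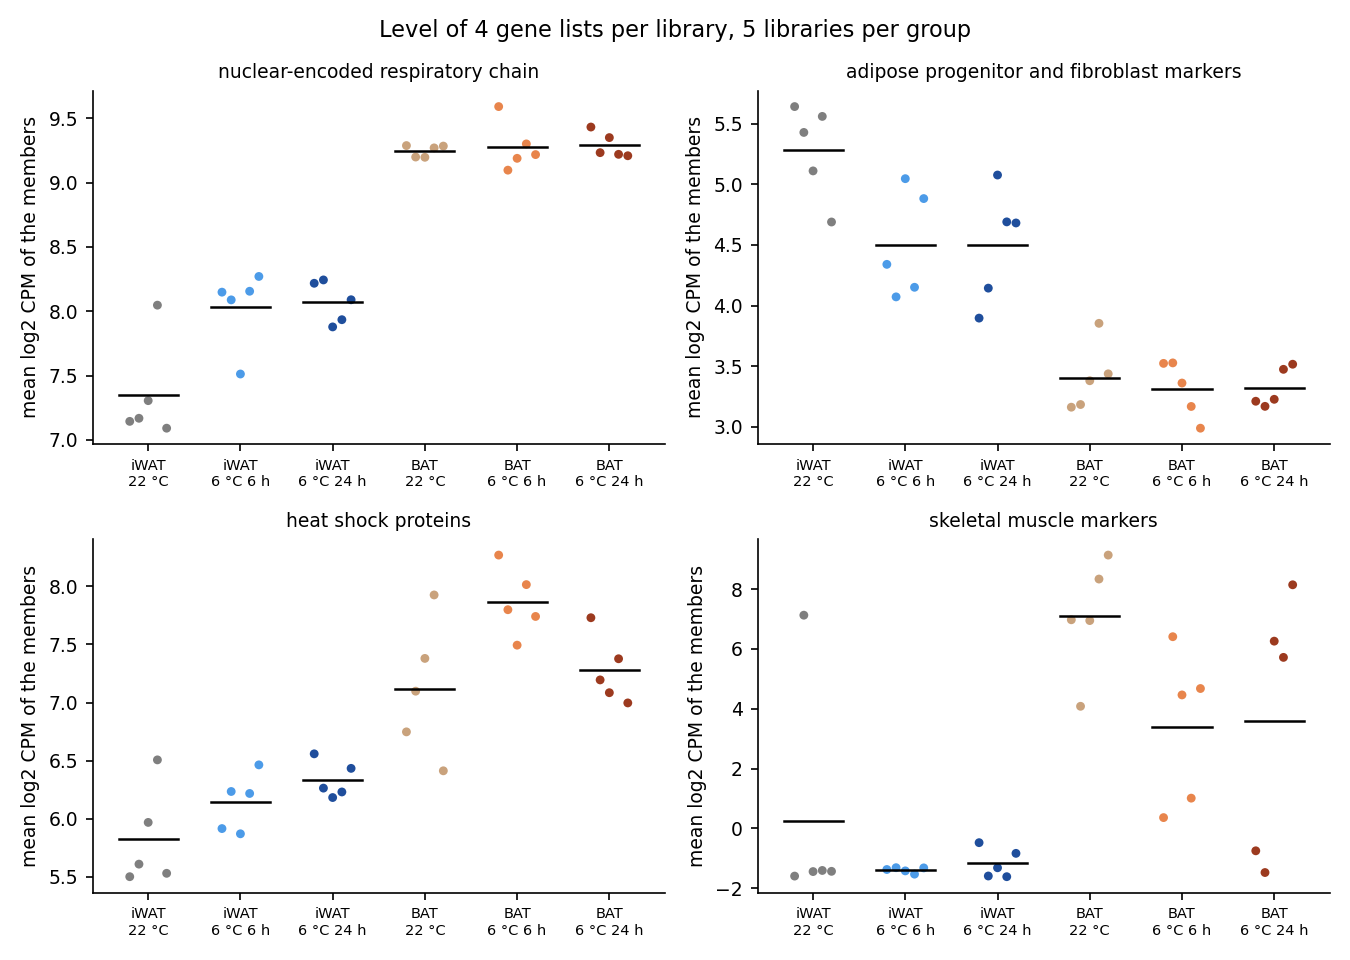
Mean log2 CPM per library of the respiratory chain, progenitor, heat shock and skeletal muscle lists in the 6 groups, with a bar at the mean of 5 libraries. For the respiratory chain, 22 °C iWAT replicate 4 stood at 8.05 and the other 4 between 7.09 and 7.3, and 22 °C iWAT replicate 2 stood at 7.12 for skeletal muscle.

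The test of the difference between tissues asked which genes responded differently to 6 h of cold in BAT and iWAT (BAT response minus iWAT response). Some genes of respiratory chain, tricarboxylic acid cycle and lipogenesis responded lower in BAT, and these list calls did not hold with an estimated correlation (adjusted p = 0.365 each). Map1b, a microtubule-associated protein, had a difference of 2.19 ± 0.26 (adjusted p = 2e-05), the calcium channel Cacna1a 2.2 ± 0.32, Cldn1 2.97 ± 0.56, the growth factor Fgf9 2.79 ± 0.6 and the natriuretic peptide clearance receptor Npr3 2.46 ± 0.49. For Bdh1 (7.14 ± 1.14) the 5 iWAT libraries at 6 h held 2 counts together, and for Hoxc9 (-4.69 ± 1.22; adjusted p = 0.117 without 22 °C BAT replicate 4) the 5 BAT libraries at 6 h held none. These sizes depend on the prior count. The other largest negative differences were Lrtm1 (-3.12 ± 0.65), Odad4 (-2.61 ± 0.66), Kng2 (-2.91 ± 0.8; adjusted p = 0.0694 without 6 h iWAT replicate 4), Sgk2 (-3.43 ± 1.06, adjusted p = 0.04) and the transporter Slco4a1 (-2.8 ± 0.83, adjusted p = 0.032). Sgk2 had 0.0515 to 0.105 without 22 °C iWAT replicate 1, 2, 3 or 5, 6 h iWAT replicate 4 or 5, 22 °C BAT replicate 2 or 3 or 6 h BAT replicate 2, 3 or 5. Slco4a1 had 0.0509 to 0.0869 without 22 °C iWAT replicate 1, 3 or 5 or 6 h iWAT replicate 4 or 5. On FPKM with pseudocount 1 they turned to 0.72 and 0.46.

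By members of the lists, the BAT response at 6 h was lower for 12 of 34 respiratory chain genes (30 adjusted over the list alone, median difference -0.63), 10 of 17 of the tricarboxylic acid cycle (16, -0.65) and 10 of 22 of de novo lipogenesis (13, -0.94), with Thrsp at -2.24 ± 0.31. It was lower for 8 of 26 of fatty acid oxidation with 1 higher (22 and 1, -0.67) and 8 of 24 of fatty acid uptake (9 lower and 1 higher, -0.39). It was also lower for 5 of 23 of glycolysis with 1 higher (15 and 1, -0.69) and 3 of 26 thermogenic genes (3, -0.99), with Ppargc1b at -1.66 ± 0.29. Camera gave adjusted p = 1.14e-13, 3.86e-09, 8.78e-08, 4.17e-08, 0.000139, 0.000248 and 0.000499, and adjusted p = 0.365 to 0.455 with an estimated correlation. Endothelial markers responded higher in BAT for 3 of 15 members (7 adjusted over the list alone, 0.38, camera adjusted p = 4.24e-05, and adjusted p = 0.365 with an estimated correlation). Heat shock proteins responded higher for 2 of 13 (2, 0.31, 0.00634, adjusted p = 0.457 with an estimated correlation, and 0.0825 without 22 °C iWAT replicate 4), with Hsp90aa1 at 1.16 ± 0.23. Branched-chain amino acid catabolism (-0.42, 2.85e-08) and lipolysis (-0.32, 0.000962) responded lower in BAT by camera and progenitor (0.8, 0.0018) and macrophage markers (0.6, 0.00166) higher. They had adjusted p = 0.365, 0.365, 0.392 and 0.392 with an estimated correlation. Camera also called mitochondrial biogenesis (-0.27, 0.00691), mitochondrially encoded genes (-0.46, 0.0102) and the integrated stress response (-0.41, 0.0168) lower and matrix genes higher (0.25, 0.0159, but 0.073 without 22 °C iWAT replicate 1). These had adjusted p = 0.392, 0.457, 0.376 and 0.508 with an estimated correlation. By fry, thermogenic genes (0.0783), heat shock proteins (0.164), progenitor (0.0858), macrophage (0.103), mitochondrially encoded (0.0858) and matrix genes (0.239) were not called. Among the libraries, 22 °C iWAT replicate 4 and 6 h iWAT replicate 3 stood apart for the respiratory chain, and 22 °C BAT replicate 4 for thermogenic and macrophage genes. So did 22 °C BAT replicate 5 for fatty acid oxidation and 6 h BAT replicate 1 for the tricarboxylic acid cycle. Acly (-2.03 ± 0.56, adjusted p = 0.022; 0.0558 without 6 h iWAT replicate 4) and Fasn (-1.34 ± 0.38, adjusted p = 0.025; 0.0547, 0.0571 and 0.0519 without 22 °C iWAT replicate 2, 6 h iWAT replicate 4 and 6 h BAT replicate 5) passed. Ucp1 (-2.54 ± 0.92, adjusted p = 0.078), Pdk4 (-1.6 ± 0.54), Dio2 (-2.05 ± 0.8), Elovl3 (-2.16 ± 0.88), Fgf21 (-1.91 ± 1.12) and Nr4a1 (-1.05 ± 0.74) did not pass. Neither did Cidea (-1.02 ± 0.56), Lep (-1 ± 0.57), Cirbp (-0.35 ± 0.22), Per1 (-0.26 ± 0.18), Rbm3 (-0.22 ± 0.14) and Ppargc1a (-0.14 ± 0.5). The response was higher in BAT for 476 genes and lower for 849. The 1325 calls became 862, 871 and 2173 without 22 °C iWAT replicates 1, 2 and 4. On FPKM, where the median difference of all genes moved from -0.02 to 0.13 or 0.19, the split was 2205 or 1525 higher and 401 or 369 lower, and 631 and 644 with upper-quartile factors.

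At 24 h the test of the difference between tissues placed Ckb (2.91 ± 0.28, adjusted p = 3.4e-07), Npr3 (3.02 ± 0.49), the sialic acid enzyme Cmah (2.78 ± 0.46), Sdf2l1 (2.6 ± 0.36) and Bdh1 (6.36 ± 0.93) higher in the BAT response. So was Plac8 (2.83 ± 0.79; adjusted p = 0.0547 without 22 °C BAT replicate 3 and 0.0903 without 24 h BAT replicate 4). The BAT response was lower for Sgk2 (-4.58 ± 1.03), Slco4a1 (-4.14 ± 0.8), Kng2 (-3.93 ± 0.79) and Cend1 (-3.4 ± 0.61). It was lower too for Fabp3 (-3.71 ± 1.06; adjusted p = 0.0547, 0.0517 and 0.0502 without 22 °C iWAT replicate 2, 24 h iWAT replicate 5 and 24 h BAT replicate 4) and Fam131c (-3.58 ± 0.86, but 0.34 on FPKM with pseudocount 1). It was also lower for Ucp1 (-3.2 ± 0.92, adjusted p = 0.031; 0.0594 and 0.0518 without 22 °C iWAT replicate 2 and 24 h BAT replicate 4) and Dio2 (-2.77 ± 0.8, adjusted p = 0.031). The same held for Fasn (-1.35 ± 0.38, adjusted p = 0.027; 0.0557 and 0.0656 without 22 °C and 24 h iWAT replicate 2) and Rbm3 (-0.57 ± 0.14, adjusted p = 0.012). Dio2 had 0.0513 to 0.0594 without 22 °C iWAT replicate 1 or 2, 24 h iWAT replicate 1, 22 °C BAT replicate 2 or 24 h BAT replicate 4. Pdk4 (-1.88 ± 0.55, adjusted p = 0.031) had 0.0508 to 0.0631 without 22 °C iWAT replicate 1, 2 or 5, 24 h iWAT replicate 4 or 5, 22 °C BAT replicate 2 or 24 h BAT replicate 1 or 4. Acly (-1.79 ± 0.56, adjusted p = 0.046) had 0.0537 to 0.122 without 22 °C iWAT replicate 1, 2 or 3, 24 h iWAT replicate 1, 2 or 4, 22 °C BAT replicate 1, 3, 4 or 5 or 24 h BAT replicate 1, 3 or 5. Nr4a1 (-2.29 ± 0.75, adjusted p = 0.056), Per1 (-0.49 ± 0.18), Fgf21 (-2.64 ± 1.1), Elovl3 (-1.91 ± 0.88), Cidea (-0.92 ± 0.56), Ppargc1a (-0.67 ± 0.51), Lep (-0.62 ± 0.58) and Cirbp (-0.14 ± 0.22) did not pass.

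Thermogenic genes responded lower in BAT at 24 h for 8 of 26 members (15 adjusted over the list alone, median difference -1.3), with Ppargc1b at -2.19 ± 0.29 and Irf4 at -3.37 ± 0.73. So did 13 of 34 respiratory chain genes (27, -0.61), 12 of 17 of the tricarboxylic acid cycle (17, -0.71) and 10 of 26 of fatty acid oxidation with 1 higher (16 and 1, -0.59). The same held for 6 of 22 of lipogenesis (12, -0.84), 6 of 23 of glycolysis (12 lower and 1 higher; -0.63) and 5 of 20 of the integrated stress response (5, -0.42). Camera's adjusted p values were 1.11e-11, 7.06e-17, 2.13e-13, 6.32e-09, 1.14e-05, 3.51e-06 and 0.00074, and adjusted p = 0.268 with an estimated correlation for each of the 7. Higher BAT responses came from the unfolded protein response (5 of 18, with 1 lower; 6 and 1 adjusted over the list alone, 0.16), macrophage markers (1 of 16, 8 adjusted over the list alone, 0.89) and interferon-stimulated genes (2 of 18, 5 adjusted over the list alone, 1.02). They had camera adjusted p = 0.00166, 8.3e-05 and 1.3e-05 and adjusted p = 0.268, 0.268 and 0.33 with an estimated correlation. Without 24 h BAT replicate 4, which stood apart in the interferon list, macrophage markers had 0.000989 and interferon-stimulated genes 0.0126. Camera further placed the BAT response lower for branched-chain amino acid catabolism (-0.29, 0.000512), biogenesis (-0.27, 0.000267), mitochondrially encoded genes (-0.36, 0.00587) and fatty acid uptake (-0.09, 0.00393, but a median of 0.05 or 0.06 on FPKM). It placed the response higher for endothelial (0.32, 0.000326), progenitor (0.59, 0.00138) and proliferation genes (0.64, 0.00353). Those 7 lists had adjusted p = 0.299, 0.268, 0.403, 0.268, 0.299, 0.299 and 0.268 with an estimated correlation. By fry, interferon-stimulated (0.0923), mitochondrially encoded (0.088), progenitor (0.0822) and endothelial genes (0.051) were not called. The 22 °C libraries named for the 6 h difference also served as controls here. The BAT response was higher for 417 genes and lower for 683. The 1100 calls became 703 without 22 °C iWAT replicate 1. On FPKM 1571 or 1076 were higher and 385 or 371 lower, with 546 and 519 under upper-quartile factors.

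The responses at 6 h and 24 h shared 1274 genes that rose and 746 that fell in iWAT (227 and 140 expected). In BAT 885 and 629 were shared (208 and 138 expected). In iWAT and BAT 0 and 34 genes went opposite ways (356 and 340 expected). Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.845 in iWAT and 0.716 in BAT. Both times share their 22 °C libraries, and simulated unchanged groups gave a mean r of 0.492 and 0.499. Unchanged genes are rarely called, so their mean of 0 and 0.05 shared risers cannot size what sharing adds. With the 22 °C libraries split 3 and 2 between the times, which also lowers power, the shared counts averaged 251.2 and 91.4 in iWAT (from 2 and 2 to 487 and 162 over 20 ways of splitting) and 440 and 291.8 in BAT (from 378 and 257 to 487 and 318). With this split r averaged 0.601 in iWAT (0.522 to 0.682) and 0.539 in BAT (0.293 to 0.639). Between tissues, which share no library, 618 genes rose and 274 fell in both at 6 h (221 and 133 expected), and 772 and 351 at 24 h (223 and 138 expected). Opposite calls numbered 78 and 62 (343 and 351 expected), and r across genes was 0.476 and 0.472.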

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

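The 6 tests of muscle, stromal share, pad sampling and clock genes were chosen after the result was seen, and the counts of splits were planned. In 306 groups of 5 libraries, 19 libraries stood far from the other 4, and chance sets apart about 1 in 20 groups.

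In iWAT at 22 °C, the mean log2 CPM of the nuclear-encoded respiratory chain genes was 8.05 in replicate 4 (others 7.09 to 7.3) and of unfolded protein response genes 6.45 (6.26 to 6.31). In replicate 2 skeletal muscle markers stood at 7.12 (others -1.59 to -1.41), creatine and calcium cycling genes at 4.11 (1.52 to 1.82) and smooth muscle markers at 5.34 (4.84 to 4.96). In iWAT at 6 h, respiratory chain genes were at 7.51 in replicate 3 (others 8.09 to 8.27), proliferation genes at 0.91 in replicate 2 (0.12 to 0.28), Fasn at 12300 CPM in replicate 4 (5630 to 7550) and Nr4a1 at 28.2 CPM in replicate 5 (3.8 to 6.28). In iWAT at 24 h, Lep was at 455 CPM in replicate 5 (others 169 to 249). In BAT at 22 °C, thermogenic genes were at 5.77 and macrophage markers at 3.26 in replicate 4 (others 6.07 to 6.18 and 2.43 to 2.6), and fatty acid oxidation at 8.32 in replicate 5 (8.47 to 8.5). In BAT at 6 h, replicate 1 stood apart with tricarboxylic acid cycle genes at 10.49 (10.26 to 10.32) and Cidea at 2180 CPM (1640 to 1790). In BAT at 24 h, mitochondrially encoded genes took 25.1% of counts in replicate 2 (24.3 to 24.5), interferon-stimulated genes were at 4.81 in replicate 4 (2.68 to 3.05), and Cirbp and Rbm3 were at 17.1 and 71.3 CPM in replicate 3 (10.6 to 12.2 and 48.1 to 54.5).

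The cold response differed between tissues for 1325 genes at 6 h and 1100 at 24 h by the test of the difference. The 6 h differences (BAT response minus iWAT response, log2) were Bdh1 7.14, Cldn1 2.97, Fgf9 2.79, Npr3 2.46, Cacna1a 2.2, Map1b 2.19, Hoxc9 -4.69, Sgk2 -3.43, Lrtm1 -3.12, Kng2 -2.91, Slco4a1 -2.8, Odad4 -2.61, Acly -2.03 and Fasn -1.34. Those at 24 h were Bdh1 6.36, Npr3 3.02, Ckb 2.91, Plac8 2.83, Cmah 2.78, Sdf2l1 2.6, Sgk2 -4.58, Slco4a1 -4.14, Kng2 -3.93, Fabp3 -3.71, Fam131c -3.58, Cend1 -3.4, Ucp1 -3.2, Dio2 -2.77, Pdk4 -1.88, Acly -1.79, Fasn -1.35 and Rbm3 -0.57.

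For the counts of called genes, the real split was compared with other splits of the same libraries. Of the 100 splits, 1 (the real one) gave as many genes for iWAT at 24 h (3145, highest other 1661), BAT at 6 h (2967, 344), BAT at 24 h (3030, 73), BAT at 24 h against 6 h (1708, 2) and BAT against iWAT (9427, 5092). As many genes came from 2 splits for iWAT at 6 h (3148, highest other 3518), from 3 for the difference at 6 h (1325, 2310) and from 2 for that at 24 h (1100, 2751). In these 8 comparisons the share of such splits was under 0.05, the bar set beforehand, which makes chance unlikely. Chance is not excluded where another split gave more genes than the real one. For iWAT at 24 h against 6 h, 7 of the 100 splits gave as many genes (1, highest other 81), so chance cannot be excluded. What set apart the splits with more genes than the real one was not tested.

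Skeletal muscle RNA varied between BAT libraries, and the groups overlapped. The 15 markers moved together, with a median pairwise r of 0.962 between genes over 15 BAT libraries after centring on the group, so skeletal muscle in some dissected pads may account for the variation. Whether BAT itself expressed less of these genes in the cold stays open, because less muscle in the pads would also lower the list mean. The exact permutation p of the list mean was 0.0476 at 6 h (difference -3.71) and 0.159 at 24 h (-3.48), where 0.0079 is the smallest possible.

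In cold iWAT, mitochondrial genes were higher and stromal lists lower. A smaller share of stromal cells as the whole cause is argued against by general adipocyte genes, whose median of 20 was 0.12 at 24 h (quartiles -0.14 and 0.37) against 0.66 for respiratory chain genes (0.51 and 0.76). At 6 h these were 0.24 (0.11 and 0.47; 7 higher and 0 lower) against 0.62 (0.57 and 0.7). The covariate of stromal lists left 4 genes called at 6 h and 381 at 24 h, so the share of stromal cells may still play a part. Pads that differ in brown-like adipocytes may contribute. Over 15 libraries, Ucp1 and the mean respiratory chain level, each centred on its group, had r = 0.633 (permutation p = 0.0402), rho = 0.604 (permutation p = 0.0233) and r = 0.747 without the 2 farthest libraries, from 100000 permutations. This correlation pools cold and 22 °C libraries, so it cannot show that pads differ whatever the temperature. At 22 °C, Ucp1 was at 783 CPM in replicate 3 and 615 in replicate 4. The respiratory chain level stood high only in replicate 4 (8.05, others 7.09 to 7.3). An effect of cold on adipocytes stays open beside such differences between pads. The counts of splits (1 of 100 at 24 h, 2 at 6 h) test only whether the groups differ, so they cannot decide between these.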

How the results depend on the processing

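The covariates for muscle and stroma were chosen after seeing the data; the other alternatives were planned. Counts of called genes stayed within 1.5 times of the reported count except as follows, and the cause was not tested where none is given. For iWAT at 6 h (3148) the stroma covariate gave 4, the muscle covariate 1610, and FPKM 4899 (pseudocount 1) and 4783 (0.1). For iWAT at 24 h (3145) the stroma covariate gave 381. The stroma covariate is built from lists that were lower in the cold, so it would also remove a response that moves with them. The drop cannot tell such a response from a change in the share of stromal cells. For iWAT at 24 h against 6 h (1) DESeq2 gave 122, FPKM 5 and 0, all 30 libraries 56, and 2 groups, the replicate block and the muscle covariate 0 each. For the difference between tissues FPKM with pseudocount 1 gave 2606 at 6 h (1325) and 1956 at 24 h (1100). DESeq2 found 35 iWAT genes moving back by 24 h and 9 moving further, where edgeR found none, and 62 of the genes called at 24 h and not at 6 h differed between the times, where edgeR found 1.

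Leaving out each library gave 1525 to 4032 genes for iWAT at 6 h, 2053 to 3646 at 24 h, 0 to 13 at 24 h against 6 h, 2274 to 3196 for BAT at 6 h, 2471 to 2870 at 24 h, 1205 to 2230 at 24 h against 6 h, 8886 to 9382 for BAT against iWAT, and 862 to 2173 and 703 to 1641 for the differences at 6 h and 24 h. With the replicate block the counts were 2881, 2959, 0, 3282, 3442, 2124, 9643, 1571 and 1241 in that order. Group-centred profiles of libraries with equal numbers correlated at -0.558 to 0.74, with 25 of 45 pairs over 0.1 and the own number closest in 21. The labels do not say what equal numbers share, so the main fits did not pair the libraries and left any such structure in the spread. Between BAT at 22 °C and 24 h the own number was closest for replicates 1, 2, 4 and 5 (r = 0.205, 0.6, 0.347 and 0.51) but not 3 (-0.086). Between iWAT at 22 °C and 24 h it was closest only for replicate 3 (0.193). Between iWAT and BAT at 24 h all 5 pairs were over 0.1 (0.11 to 0.543) with the own number closest in 4. At 6 h 4 pairs were (-0.075 to 0.74) and at 22 °C 1 was (-0.056 to 0.33). That hints at a shared animal or batch across tissues in the cold, which the block, joining equal numbers over all groups, does not test. The block left 616 of 634 values of named genes on their side of the threshold. Among those printed, the others were Wdr6 in iWAT at 24 h against 6 h (adjusted p = 0.153), Eno3 in iWAT at 24 h (0.156), Nr4a1 in BAT at 24 h against 6 h (0.0546), Sgk2 in the difference at 6 h (0.053), Cidea in iWAT at 24 h (0.0365), Pdk4 in the difference at 6 h (0.0427) and Nr4a1 in the difference at 24 h (0.0406). The block left 290 of 297 list results on their side. The others were heat shock proteins and cholesterol genes in the difference at 24 h (adjusted p = 0.0518 each), lipolysis in iWAT at 24 h (0.0584), lipolysis (0.0587), creatine and calcium cycling and lymphocyte markers (0.0629 each) in BAT at 24 h against 6 h, and clock genes in BAT at 24 h (0.0344).

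Among named genes called in the main fit or in the alternative, the values that changed sign were Mrc1 in iWAT at 6 h (0.04 with the stroma covariate), Per1 between tissues (-0.26 and -0.28 on FPKM), and on FPKM with pseudocount 1 Sgk2 (0.72) and Slco4a1 (0.46) in the difference at 6 h and Fam131c (0.34) at 24 h. Lists that changed direction, called in the main fit or in the alternative, were progenitor (adjusted p = 0.0689 at 6 h and 0.882 at 24 h) and macrophage markers (0.0689 and 0.0044) in iWAT with the stroma covariate, which contains them, skeletal muscle in BAT at 6 h (0.811 with the muscle covariate, which is that list), and skeletal muscle in the differences without 22 °C iWAT replicate 2 (0.000385 at 6 h and 0.000292 at 24 h), the library rich in muscle RNA. Over single libraries left out, those 2 adjusted p values reached 0.984 and 0.999. Of the values of named genes, DESeq2 left 620 of 629 on the same side of the threshold and, where called, in the same direction, upper-quartile factors 624 of 634, FPKM with pseudocount 1 568 of 634, the muscle covariate 601 of 634, the stroma covariate 43 of 184 and single libraries left out 7433 of 7970. For the lists these counts were 163 of 297 with an estimated correlation, 239 of 297 with fry, 55 of 66 with the stroma covariate and 3436 of 3630 with single libraries left out. Besides the lists that changed direction, the stroma covariate ended the iWAT calls at 6 h of de novo lipogenesis (0.683), cholesterol (0.807), lipolysis (0.177), matrix (0.191) and heat shock genes (0.0689), and at 24 h of lipolysis (0.315) and mitochondrially encoded genes (0.147). Depth limits genes with few counts, whose fitted folds depend on the prior count.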

Other observations

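The tests of clock genes here were chosen after the result was seen. Clock genes moved in both tissues in the cold, of which Bmal1 and Dbp were picked after their values were seen. Bmal1, an activator of the clock, rose in iWAT (1.5 ± 0.31 at 6 h and 1.37 ± 0.31 at 24 h) and in BAT (2.44 ± 0.28 and 1.33 ± 0.28), and Dbp, an output gene of the clock, fell in iWAT (-0.4 ± 0.13 and -0.55 ± 0.13) and in BAT (-1.3 ± 0.1 and -0.51 ± 0.1). The list as a whole was not called by camera: 3 of 17 genes rose and 2 fell in iWAT at 6 h, 3 and 4 at 24 h, 5 and 5 in BAT at 6 h and 2 and 6 at 24 h. Across 17 clock genes, which are not independent replicates, the responses of the tissues correlated at r = 0.887 (rho = 0.882) at 6 h and r = 0.74 (rho = 0.613) at 24 h, and 2 and 3 genes of the list differed between tissues. Collection at different times of day may produce such a pattern, as may cold acting on the clock, and the labels give no collection time, so these cannot be told apart.

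In the cold groups against 22 °C, 6 further lists were not called by camera. Acute inflammation had medians of -0.42 and -0.15 in iWAT and 0.08 and 0.26 in BAT at 6 h and 24 h, secreted factors of adipose tissue 0.15, -0.1, -0.14 and -0.17, Schwann cell and nerve markers -0.37, -0.28, -0.32 and -0.11, smooth muscle and pericyte markers -0.26, -0.06, -0.17 and -0.14, lymphocyte markers -0.77, -0.33, -0.96 and -0.09, and brown adipocyte identity genes 0.11, 0.14, 0.01 and 0.05. The epithelial and skin list had fewer than 5 tested members and no test. Secreted factors were lower by camera in the BAT response than in the iWAT response at 6 h (adjusted p = 0.0441) and 24 h (0.0211), brown adipocyte identity genes at 24 h (0.0204), and immediate early genes were higher at 6 h (0.0397). Heat shock proteins and cholesterol genes were lower at 24 h (0.0487 each). These had adjusted p = 0.365, 0.268, 0.268, 0.457, 0.6 and 0.637 with an estimated correlation, and by fry immediate early genes had 0.225, heat shock proteins 0.215 and cholesterol genes 0.276. Each was lost without single libraries. Secreted factors at 6 h had 0.05 to 0.0712 without 22 °C iWAT replicate 3, 4 or 5, 6 h iWAT replicate 1, 3 or 5, 22 °C BAT replicate 3 or 4 or 6 h BAT replicate 3. At 24 h they had 0.0518 and 0.0586 without 24 h iWAT replicate 5 and 24 h BAT replicate 2. Brown adipocyte identity had 0.0626 without 22 °C iWAT replicate 5. Immediate early genes had 0.0536 to 0.134 without 22 °C iWAT replicate 3 or 4, 6 h iWAT replicate 1 or 3, 22 °C BAT replicate 3, 4 or 5 or 6 h BAT replicate 3. Heat shock proteins had 0.0703 to 0.316 without 22 °C iWAT replicate 1, 2 or 5, 24 h iWAT replicate 1 or 5, 22 °C BAT replicate 3 or 4 or 24 h BAT replicate 2, 3 or 5. Cholesterol genes had 0.0523 to 0.287 without 22 °C iWAT replicate 2 or 4, 24 h iWAT replicate 1, 2 or 5, 22 °C BAT replicate 1, 3 or 5 or 24 h BAT replicate 3 or 4.

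In iWAT at 22 °C replicate 2, the muscle genes Acta1 and Tnnt3 were at 666 and 477 CPM.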
